A study of Rattus norvegicus with 15 samples.

How the data were processed

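RNA was sequenced from the injured side of the lumbar spinal cord of adult male Sprague-Dawley rats, in 5 groups of 3 libraries, 15 libraries in all. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit. Whether strand was kept in counting is not given in the sources used here, so reads of overlapping or antisense genes may be assigned to either gene, and near-identical gene copies may share reads.

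The authors deposited raw counts per gene, as whole numbers, 1 table per library. Per the submitters' processing notes, the genome build was rn4 and DESeq2 version 1.16.1 was among the tools. The aligner, the counting program and the annotation are not given in the sources used here. Each table held 34202 rows, of which 32883 carried an Ensembl rat identifier and 1319 were loci that the authors labelled only by a running number. No row held a total or unassigned reads. The labels say that 7 rats made up each ligated group and that 3 per group were sequenced, so libraries are taken as separate rats.

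The tables do not pair identifiers with gene symbols. The reference table used here (GRCr8, 47357 genes) gave an Ensembl identifier for 0 genes, so 0 identifiers could be matched to a symbol. The 29 gene lists fixed before the data were examined (cell types, injury, glial, immune, receptor and other groups) were therefore not tested, and the planned naming of genes by symbol was not possible. The rule fixed beforehand only counts loci without a symbol. As an exception, 4 identifiers are printed, 2 that rose and 2 that fell; they were chosen after their values were seen, as called genes of small p in the comparisons that called any gene. Coordinates are not given.

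Library totals ranged from 15093246 to 22757104 counts. With edgeR 4.0.16 in R 4.3.3, genes were kept by filterByExpr with its minimum count of 10, which left 16522 genes, 911 of them without an Ensembl identifier. Libraries were scaled by TMM (trimmed mean of M-values), and CPM below means counts scaled by library size in edgeR's cpm function, after that step. A quasi-likelihood negative binomial model (glmQLFit and glmQLFTest) was fitted to all 15 libraries with a coefficient for each of the 5 groups, so that the groups shared an estimate of the spread with 10 residual degrees of freedom. The common biological coefficient of variation was 15.4%. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, in each of 11 comparisons. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Principal components were computed on log2 CPM with a prior count of 2. Counts were also simulated for all 15 libraries over 16522 genes, from each gene's mean level over all groups and its fitted spread. Changes were placed in the CCI libraries, and genes were drawn independently. CCI against sham then recovered 35.8% of 67 genes changed by 1.5-fold, 56.7% of 67 changed by 2-fold and 87.9% of 66 changed by 4-fold. There were 3 false calls over all sizes.

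The share of genes that moved back toward sham in a treated group, and the correlation of treatment effects, were set against 100 sets of libraries rebuilt from the residuals, since these comparisons share the CCI libraries. For the resampled shares and for the overlap of gene lists the genes were ranked or tested with limma 3.58.1 on log2 CPM. Libraries of the same group differed by far more than sampling noise, with a chi-square per gene of 7.04 to 27.0 over the 15 same-group pairs, so none was counted as a repeat of another.

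Alternatives fixed before the data were examined were DESeq2 1.42.0, limma voom with and without sample quality weights, RLE and upper-quartile scaling, no filter on low counts, a mean count of at least 50, only the groups compared, an adjusted p under 0.1, an absolute log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were a surrogate variable from sva 3.50.0, the share of counts of the 3 most abundant genes as a covariate, the exclusion of rows without an Ensembl identifier, and 2 contrasts over all ligated groups for the presence of either component.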

Results

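The series profiled gene expression in the L4-L6 spinal cord of rats with chronic constriction injury (CCI), in which loose ligatures around the sciatic nerve produce neuropathic pain. Sham rats had the nerve exposed and not ligated. Ligated rats were left untreated or received Yuan-Hu Zhi Tong Prescription (YZP) or either of the preparations named YH and BZ, which the title places in a study of how the parts of the prescription work together. The daily doses differed, at 10.8 g crude drug per kg for YZP, 7.2 for YH and 3.6 for BZ, given for 5 days from postoperative day 6 to day 10, when tissue was taken. Each of the 5 groups held 3 libraries. Total counts per library ranged from 19650947 to 20446353 in sham, 17616561 to 22757104 in CCI, 15605935 to 20612814 in CCI+YZP, 15093246 to 20711139 in CCI+YH and 18027835 to 19910603 in CCI+BZ. Genes are given by identifier, since the tables do not pair identifiers with symbols.

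Sham and CCI libraries lay apart on the first principal component of log2 CPM, which held 20.8% of the variance. Sham libraries scored -28.7, -25.3 and -22.7, and CCI libraries scored 17.3, 9.16 and 31.1. Each treated group was spread along this component. CCI+YZP libraries scored -9.77, 22.9 and -10.1, CCI+YH libraries 13.9, -10.1 and 25.2, and CCI+BZ libraries 26.8, -14.4 and -25.1. The second component held 8.54% of the variance.

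**Figure D1:**
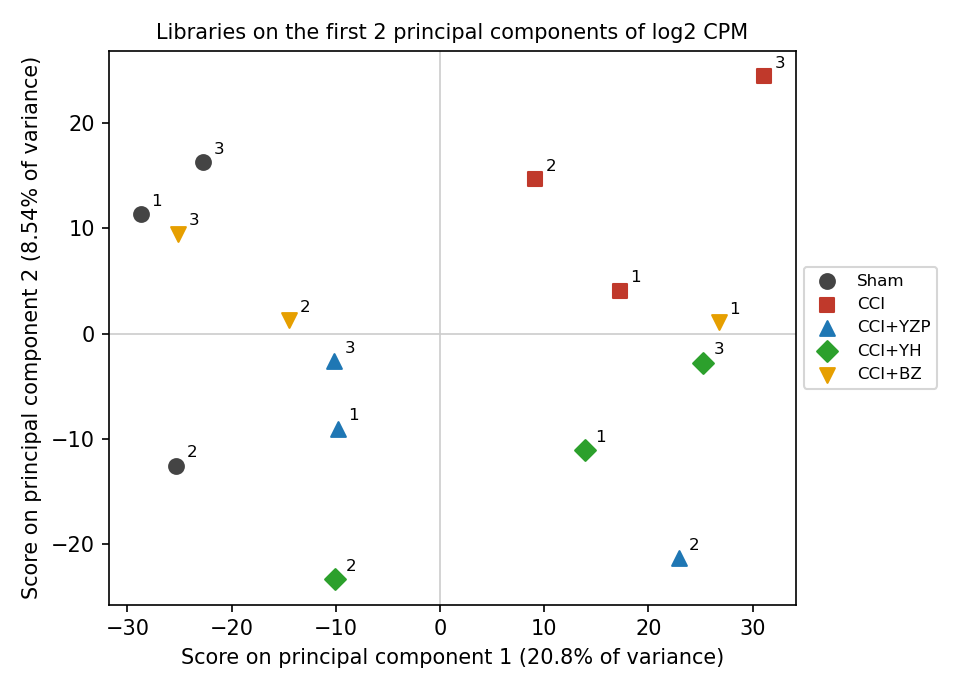
Scores of the 15 libraries on principal components 1 (x axis) and 2 (y axis) of log2 CPM, 1 point per library, coloured by group and numbered by replicate. The 3 sham libraries lie between -28.7 and -22.7 on component 1 and the 3 CCI libraries between 9.16 and 31.1, while each treated group has libraries on both sides of 0.

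The comparison of CCI with sham asks what nerve ligation changed. ENSRNOG00000011427 fell from 92.3 ± 4.54 CPM in sham to 59.8 ± 4.72 CPM in CCI (SD, n = 3 each), a log2 fold change of -0.63 (SE 0.067, edgeR adjusted p = 0.00382), with every CCI library below every sham library. It was 1 of 3 genes called, and all 3 fell. At an unadjusted p under 0.05, 2958 genes differed (1580 higher and 1378 lower in CCI), where 826.1 are expected with no effect, and 54 had an adjusted p under 0.1 (30 higher, 24 lower). The 3 most abundant genes took 8.95% ± 0.578 of the counts in sham and 7.29% ± 0.441 in CCI. The number of called genes depended on the model. DESeq2 called 484 genes (271 higher, 213 lower), edgeR on these 2 groups alone called 428 (292 higher, 136 lower), and 237 genes were called by both, with the same sign in all 237. Limma voom called 3 genes, and 2074 with sample quality weights. Of the 484 genes from DESeq2, 130 had an absolute log2 fold change of at least 1, of which 114 were higher and 16 lower in CCI. Without CCI+BZ replicate 1 the shared fit called 193 genes, and without Sham replicate 3 it called 12. It called 8 without CCI+BZ replicate 3, 7 without CCI+YH replicate 3, 6 without CCI+YH replicate 2, and 1 without any of Sham replicate 1, CCI replicate 1, CCI replicate 2 or CCI+YH replicate 1. The call of ENSRNOG00000011427 held without each library in turn (adjusted p 0.00386 to 0.0424), and was lost with a surrogate variable (adjusted p = 0.216) or with the share of the 3 most abundant genes as a covariate (adjusted p = 0.061), the highest values over its alternatives, which reached down to 1.85e-13. Its log2 fold change was -0.59 in both of these fits, and its SE was 0.0885 and 0.0821 in place of 0.0666. Its unadjusted edgeR p went from 2.31e-07 to 1.34e-05 and 7.39e-06. The adjusted p also depends on the p of all genes, of which 1057 and 1142 were under 0.05 in place of 2958.

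The effect of the prescription was read from CCI+YZP against CCI. ENSRNOG00000010706 rose from 11.3 ± 0.679 CPM in CCI to 22.1 ± 1.74 CPM in CCI+YZP (SD, n = 3 each), a log2 fold change of 0.97 (SE 0.114, edgeR adjusted p = 0.0132), and sham stood at 11.3 ± 0.716 CPM. The lowest CCI+YZP library, at 20.2 CPM, lay above the highest CCI library, at 11.9 CPM. It was the only gene called by the shared edgeR fit, where 1146 genes had an unadjusted p under 0.05 (523 higher, 623 lower) against 826.1 expected. DESeq2 called 20 genes (9 higher, 11 lower), this gene among them, and limma voom with quality weights and edgeR without a filter on low counts each called 2. The call was lost without CCI replicate 1 (adjusted p = 0.095), CCI replicate 2 (0.134), CCI+YZP replicate 1 (0.0526) or CCI+YZP replicate 3 (0.124), and with only the 2 groups in the fit (0.0775), in a range of 4.41e-10 to 0.134 over its alternatives. The count was 0 without CCI replicate 1, CCI replicate 2 or CCI+YZP replicate 3, 2 without CCI replicate 3 and 3 without CCI+YZP replicate 2, and the 1 gene called without CCI+YZP replicate 1 was another gene.

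For YH alone and BZ alone, the shared edgeR fit called 0 genes against CCI. For CCI+YH, 923 genes had an unadjusted p under 0.05 (482 higher, 441 lower), DESeq2 called 13 (3 higher, 10 lower), and limma voom called 0 with or without quality weights. For CCI+BZ, 1095 genes had an unadjusted p under 0.05 (560 higher, 535 lower), DESeq2 called 23 (6 higher, 17 lower), and limma voom called 0 with or without quality weights. ENSRNOG00000013548 had the smallest p in CCI+YH against CCI, with 73.9 ± 36.8 CPM in CCI and 4.69 ± 0.524 CPM in CCI+YH (SD, n = 3 each), a log2 fold change of -3.98 (SE 0.582) that did not pass the adjustment (edgeR adjusted p = 0.15). ENSRNOG00000011427 had the smallest p in CCI+BZ against CCI, at 82.5 ± 3.89 CPM in CCI+BZ against 59.8 ± 4.72 CPM in CCI, a log2 fold change of 0.47 (SE 0.0666) with an adjusted p of 0.12. For CCI+YH against CCI, 1 gene was called in the fit of the 2 groups (adjusted p = 0.036) and 1 without a filter on low counts (0.0222), which called 2 for CCI+BZ against CCI. For CCI+YH, 1 gene was called without Sham replicate 3 and 1 without CCI replicate 3, and for CCI+BZ 4 genes were called without CCI replicate 2.

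The prescription and its parts were then compared with each other, at doses that differed. ENSRNOG00000021824 was higher in CCI+YZP, at 149 ± 2.41 CPM, than in CCI+BZ, at 88.8 ± 2.35 CPM (SD, n = 3 each), a log2 fold change of 0.75 (SE 0.0808, edgeR adjusted p = 0.00494). ENSRNOG00000010706 was also higher in CCI+YZP than in CCI+BZ, at 22.1 ± 1.74 against 12.4 ± 1.68 CPM (log2 fold change 0.83, SE 0.114, adjusted p = 0.0234). They were 2 of 3 genes called between CCI+YZP and CCI+BZ, all higher in CCI+YZP, and 842 genes had an unadjusted p under 0.05 (434 higher, 408 lower). DESeq2 called 23 genes (15 higher, 8 lower), all 3 of these among them, as they were among the 5 called with the covariate and the 5 called without a filter on low counts. The call of ENSRNOG00000021824 was lost without CCI+BZ replicate 2 (adjusted p = 0.0669, the highest over its alternatives, which reached down to 9.77e-14). The call of ENSRNOG00000010706 was lost without CCI replicate 2 or any library of CCI+YZP or CCI+BZ except CCI+BZ replicate 3 (adjusted p 0.0507 to 0.196), and was lost in the fit of the 2 groups (0.287, the highest over its alternatives, which reached down to 4.08e-07), where 1 of the 3 genes was still called. The number called was 0 without CCI+BZ replicate 2 and 1 without CCI+YZP replicate 2 or CCI+BZ replicate 1.

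Between CCI+YH and CCI+BZ, 7 genes were called, 5 higher and 2 lower in CCI+YH, and 899 had an unadjusted p under 0.05. ENSRNOG00000021824 was higher in CCI+YH, at 131 ± 15.7 against 88.8 ± 2.35 CPM (log2 fold change 0.56, SE 0.0808, edgeR adjusted p = 0.0237). ENSRNOG00000013548 was lower in CCI+YH, at 4.69 ± 0.524 against 81.3 ± 46.2 CPM (log2 fold change -4.11, SE 0.584, adjusted p = 0.0237), and the 3 CCI+BZ libraries held 131, 73.9 and 39.3 CPM. ENSRNOG00000011427 was lower in CCI+YH, at 61.5 ± 2.86 against 82.5 ± 3.89 CPM (log2 fold change -0.42, SE 0.0668, adjusted p = 0.0473). DESeq2 called 39 genes (26 higher, 13 lower), all 7 among them, limma voom called 2, or 4 with quality weights, the covariate gave 11 with all 7 among them, and the fit of the 2 groups alone called 1, which was not among the 7. The number called was 0 without CCI+YH replicate 1, CCI+BZ replicate 1 or CCI+BZ replicate 2, 1 without CCI+BZ replicate 3, 3 without CCI+YH replicate 3, and 4 without Sham replicate 1 or CCI replicate 3. Each of these 3 identifiers lost its call with some library left out. For ENSRNOG00000011427 this held for each library except CCI replicate 1 and CCI replicate 2, with an adjusted p up to 0.295. For ENSRNOG00000013548 it held for each CCI+YH library, CCI+BZ replicate 1 and CCI+BZ replicate 2 (0.065 to 0.192). For ENSRNOG00000021824 it held for Sham replicate 1, CCI replicate 3, CCI+YH replicates 1 and 3 and each CCI+BZ library (0.0554 to 0.182). Over all alternatives the adjusted p ranged from 2.83e-05 to 0.295, from 2.5e-09 to 0.305 and from 2.87e-07 to 0.239 in that order. In limma voom without quality weights none of these 3 identifiers was called. With quality weights the 4 called genes were all among the 7, with 3 higher and 1 lower in CCI+YH. The lower gene was thus ENSRNOG00000011427 or ENSRNOG00000013548.

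CCI+YZP and CCI+YH did not differ in any gene that passed the adjustment. EdgeR called 0 genes, 588 had an unadjusted p under 0.05 where 826.1 are expected, DESeq2 called 2 (1 higher, 1 lower), and limma voom called 0 with or without quality weights. The difference for ENSRNOG00000013548, at 8.37 ± 2.85 CPM in CCI+YZP and 4.69 ± 0.524 CPM in CCI+YH, had a 95% interval of -0.51 to 2.15 on the log2 scale. For ENSRNOG00000011427 the interval was -0.13 to 0.16, and for ENSRNOG00000010706, which stood at 14.5 ± 1.73 CPM in CCI+YH, it was 0.36 to 0.85 (SE 0.113, edgeR adjusted p = 1.00). With each library left out in turn, edgeR called a gene only without CCI+YH replicate 2, when 1 was lower in CCI+YZP. The test of whether the effect of YZP departed from the sum of the effects of YH and BZ on the log2 scale called 0 genes in edgeR, with 667 at an unadjusted p under 0.05, 0 in limma voom with or without quality weights, and 6 in DESeq2 (4 higher, 2 lower).

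**Figure D2:**
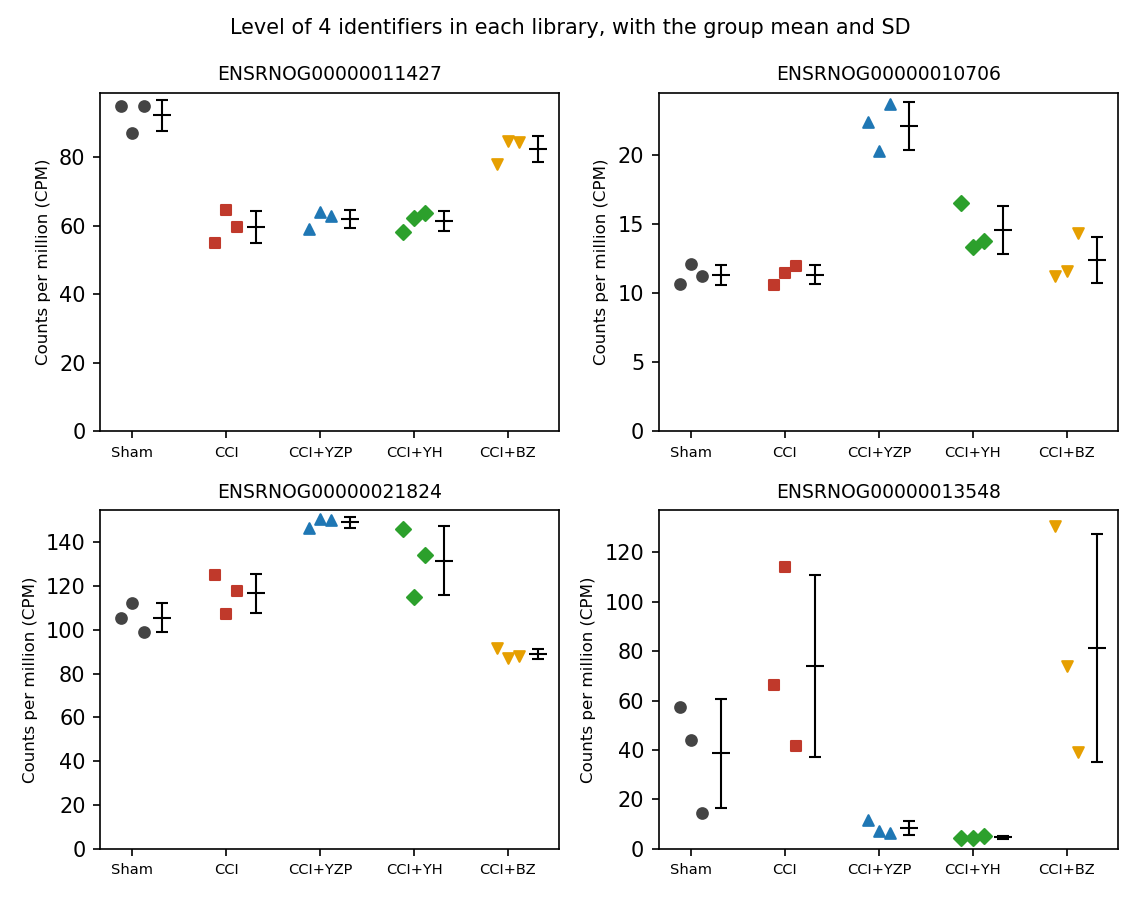
Level of 4 identifiers in CPM (y axis, linear, from 0) in each library of the 5 groups (x axis), with black marks for the group mean and bars for 1 SD (n = 3). ENSRNOG00000011427 is at 92.3 CPM in sham, at 59.8 to 62.1 in CCI, CCI+YZP and CCI+YH and at 82.5 in CCI+BZ, and ENSRNOG00000013548 is at 8.37 in CCI+YZP and 4.69 in CCI+YH against 81.3 in CCI+BZ.

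Against sham, treated groups were compared to see which differences from uninjured cord they held. ENSRNOG00000011427 was lower than in sham in CCI+YZP, at 62.1 ± 2.65 CPM (log2 fold change -0.57, SE 0.0667, edgeR adjusted p = 0.00689), and in CCI+YH, at 61.5 ± 2.86 CPM (-0.59, SE 0.0668, adjusted p = 0.00512). In CCI+BZ its log2 fold change against sham was -0.16 (SE 0.0661, adjusted p = 0.604). In all, 11 genes were called in CCI+YZP (5 higher, 6 lower), 7 in CCI+YH (3 higher, 4 lower) and 0 in CCI+BZ. Unadjusted p was under 0.05 for 1813, 2159 and 1294 genes in that order, DESeq2 called 189, 235 and 24, and limma voom called 10, 7 and 0, or 553, 864 and 2 with quality weights. Fits of only the groups compared called 38, 15 and 3, with 8 of the 11 genes among the 38 and 3 of the 7 among the 15. Without a filter on low counts 15, 11 and 0 were called. Without CCI+BZ replicate 1 the counts were 44 and 101 for CCI+YZP and CCI+YH, and without CCI+BZ replicate 3 they were 31 and 13. Without Sham replicate 1 they were 0 and 2, and ENSRNOG00000011427 then had an adjusted p of 0.0625 in CCI+YZP, the highest over its alternatives, which reached down to 1.73e-10. For CCI+YZP the count was 4 without CCI+YZP replicate 1 or 3 and 3 without CCI+YZP replicate 2, and for CCI+YH it was 3 without any of its own libraries. For CCI+BZ it was 2 without CCI+BZ replicate 3 and 1 without Sham replicate 2, CCI replicate 3 or CCI+YH replicate 3. With a surrogate variable CCI+YZP gave 14 genes (7 of the 11 among them) and CCI+YH gave 1, and with the share of the 3 most abundant genes as a covariate they gave 15 (7 of the 11) and 23 (all 7). In CCI+YH, ENSRNOG00000011427 had an adjusted p of 0.0638 with the surrogate variable, the highest over its alternatives, which reached down to 4.99e-11. Its log2 fold change there was -0.56 (SE 0.0821) in place of -0.59 (SE 0.0668), and its unadjusted edgeR p went from 5.35e-07 to 1.15e-05. The adjusted p also depends on the p of all genes, of which 1343 were under 0.05 in place of 2159.

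Whether treatment moved genes back toward sham was read from the sign of each gene's change. The 3 genes that fell in CCI, ENSRNOG00000011427 among them, all had a positive log2 fold change against CCI in each of the 3 treated groups. None of them was called there. For ENSRNOG00000011427 it was 0.056 in CCI+YZP (95% interval -0.088 to 0.20), 0.041 in CCI+YH (-0.10 to 0.19) and 0.47 in CCI+BZ. Among the 200 genes with the smallest p in CCI against sham, 86.5% moved opposite to the injury in CCI+YZP, 87% in CCI+YH and 98% in CCI+BZ. These are signs of group effects, and single libraries differed. Each treated group had libraries on both sides of 0 on the first principal component, as in CCI+BZ (26.8, -14.4 and -25.1). The comparison of CCI with sham and that of treatment with CCI both use the CCI libraries, so a high share arises with no treatment effect. With genes ranked by limma the observed shares were 88.5%, 88.5% and 99%. Resampled libraries that kept the injury effect and had no treatment effect gave means of 71.2%, 73.3% and 73.8%. Shares as large as the observed came up in 21, 22 and 0 of 100 draws. With no effect at all the means were 87.4%, 90.3% and 89.0%. The lower and upper bounds over those draws were 36.6% and 100%, 49.7% and 100%, and 53.6% and 100%. All 3 observed shares lay within these bounds. Neither kind of draw is an exact reference. Draws that kept the injury effect used the observed difference between CCI and sham, its chance part included, which can lower their shares. Draws with no effect at all left out an injury effect, while 2958 genes had an unadjusted edgeR p under 0.05 in CCI against sham, where 826.1 are expected. The result for BZ thus depended on whether the injury effect was kept, and it is not used to claim a reversal. The CCI group is too small to be split, so part of any excess may come from the shared libraries.

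The effects of the 3 treatments against CCI were correlated across genes, which are not independent replicates. Pearson's r was 0.609 for YZP with YH, 0.608 for YZP with BZ and 0.560 for YH with BZ. Unchanged groups that shared the CCI libraries gave means of 0.459, 0.477 and 0.466, with values as large in 26, 23 and 32 of 100 draws. The covariances were 0.0587, 0.0597 and 0.0535, against 0.0399, 0.0412 and 0.0392 in the unchanged groups, and values as large came up in 19, 17 and 24 of 100 draws. Of the 523 genes higher in CCI+YZP and the 482 higher in CCI+YH at an unadjusted p under 0.05, 165 were shared, where independent lists would share 15.3. Of the 623 and 441 lower genes 187 were shared, against 16.6. For CCI+YZP with CCI+BZ 150 higher and 142 lower genes were shared, against 17.7 and 20.2, and for CCI+YH with CCI+BZ 133 and 106, against 16.3 and 14.3. Part of each excess over independent lists may come from the shared CCI libraries. With limma the shared genes numbered 156 higher and 173 lower for YZP with YH, 148 and 141 for YZP with BZ, and 124 and 97 for YH with BZ. Unchanged groups that shared the CCI libraries gave means of 86.3 and 88.6, 86.3 and 87.6, and 74.1 and 74.0, and as many came up in 18 and 13, 18 and 24, and 20 and 24 of 100 draws.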

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

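The test on genes absent from sham was chosen only after the result was seen. A response that differed between treatments was found for 3 genes between CCI+YZP and CCI+BZ and for 7 genes between CCI+YH and CCI+BZ, by the direct test of the difference. Groups of 3 libraries were not examined for outliers.

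Groups of 3 against 3 libraries make 10 splits, too few for a share under 0.05. For CCI+YZP against CCI+BZ the real split called 3 genes and the highest of the other splits 1, with 1 of the 10 splits as large. For CCI+YH against CCI+BZ the real split called 7 genes and the highest other split 349, with 2 of the 10 splits as large. That split set CCI+YH replicates 1 and 3 with CCI+BZ replicate 1 against CCI+YH replicate 2 with CCI+BZ replicates 2 and 3, which are the libraries above and below 0 on the first principal component. It points to a structure of the samples that the treatment labels do not follow.

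This structure is the axis that parts sham from CCI and along which treated libraries of each group also lie apart. Library depth stays open. After thinning every library to the total of the smallest, the gap between CCI and sham was 0.992 of its size. The range was 0.988 to 0.996 over 5 thinnings. Totals in CCI (17616561 to 22757104) lay on both sides of those in sham (19650947 to 20446353), so thinning could hardly move this gap. The spread within treated groups was not measured after thinning. Treated libraries above 0 on the axis held 15093246 to 18027835 counts. Those below 0 held 19146341 to 20711139, except CCI+YZP replicate 1 at 15605935. Abundant genes that take a varying share of the counts stay open: leaving out the 100 most abundant of 16522 equally weighted genes left the gap at 1.00 of its size. A value over 0.8 had been set beforehand to argue against them, but so few genes could hardly move the gap, so this value is not used to argue either way. The share of the 3 most abundant genes was 7.99%, 7.02% and 8.56% in the CCI+YZP libraries, 7.91%, 9.09% and 7.38% in CCI+YH and 6.76%, 8.43% and 9.18% in CCI+BZ, lowest in each treated group in the library with the highest score on the axis. The same held in CCI, where replicate 3 had the highest score and the lowest share (6.78%, against 7.55% and 7.53%). In sham the order was different, as replicate 3 had the highest score and the highest share (9.60%) and replicate 2 the lowest share (8.49%). As a covariate the share took CCI against sham from 3 called genes to 0 and from 2958 genes at an unadjusted p under 0.05 to 1142. For ENSRNOG00000011427 the log2 fold change went from -0.63 (SE 0.0666) to -0.59 (SE 0.0821), and the median SE over all genes from 0.126 to 0.144. Fold changes of the other genes in this fit were not examined, so the loss of calls is not used for or against this explanation. A dissection or preparation difference not given in the labels and an injury response that varies between rats cannot be told apart: 5 genes were under 0.5 CPM in all sham libraries and at 2 CPM or more in all CCI libraries (0 in the other 19 of 20 ordered splits). In 5 of 9 treated libraries, CCI+YZP 1 and 3, CCI+YH 2 and CCI+BZ 2 and 3, at most 25% of these genes reached 2 CPM. In CCI+YZP 2, CCI+YH 3 and CCI+BZ 1 all 5 did, and 3 of 5 did in CCI+YH 1. Such a mix is what both explanations allow. A dissection difference was also expected to give as many such genes in other splits of the 6 libraries, and this was not seen, but a difference that followed the 2 groups would not give them. The labels give no batch, and an effect of treatment in some rats stays open and untested.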

How the results depend on the processing

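The surrogate variable, the covariate, the exclusion of rows without an Ensembl identifier and the contrasts for the presence of YH or BZ were chosen after seeing the data. Counts of called genes are listed in the order CCI, CCI+YZP, CCI+YH and CCI+BZ (first against sham, the next 3 against CCI), YZP against YH, YZP against BZ, YH against BZ, the departure from additivity, and YZP, YH and BZ against sham. As reported they were 3, 1, 0, 0, 0, 3, 7, 0, 11, 7 and 0. They stayed within 1.5 times of these with RLE or upper-quartile scaling, a mean count of at least 50, and without the rows lacking an Ensembl identifier. DESeq2 gave 484, 20, 13, 23, 2, 23, 39, 6, 189, 235 and 24. Limma voom gave 3, 1, 0, 0, 0, 3, 2, 0, 10, 7 and 0, and with sample quality weights 2074, 2, 0, 0, 0, 3, 4, 0, 553, 864 and 2. An adjusted p under 0.1 gave 54, 2, 0, 0, 0, 7, 10, 0, 81, 32 and 0. An absolute log2 fold change of at least 1 left 0, 0, 0, 0, 0, 0, 2, 0, 0, 0 and 0. No filter on low counts gave 4, 2, 1, 2, 0, 5, 8, 0, 15, 11 and 0. With only the groups compared the counts were 428, 0, 1, 0, 0, 3, 1, 0, 38, 15 and 3. The surrogate variable gave 0, 1, 0, 0, 0, 3, 10, 0, 14, 1 and 0, and the covariate 0, 1, 0, 0, 0, 5, 11, 0, 15, 23 and 0. Leaving out each library in turn gave ranges of 1 to 193, 0 to 3, 0 to 1, 0 to 4, 0 to 1, 0 to 4, 0 to 8, 0 to 0, 0 to 44, 2 to 101 and 0 to 2. The looser threshold and the fold limit change the counts by construction, and for the other settings the cause was not tested.

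With the replicate number as a block the counts were 2, 2, 1, 0, 0, 2, 2, 0, 5, 4 and 0, with 1 of the 3 genes for YZP against BZ still called, and without ENSRNOG00000010706 there (adjusted p = 0.0675). The numbers do not pair the libraries: same-numbered libraries of different groups had residual correlations of -0.167 to 0.143, over 0.1 in 3 of 30 pairs, and 4 of 15 libraries correlated best with their own number.

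The share of called CCI genes with the opposite sign under treatment, 100% in each treated group, ranged over the left-out libraries from 50% to 100% for YZP, 0% to 100% for YH (0% without CCI replicate 1, which left 1 called gene) and 50% to 100% for BZ. In DESeq2 it was 90.7%, 85.5% and 97.7%. The correlations of treatment effects were 0.643, 0.632 and 0.551 over genes with a mean count of at least 50. For the presence of YH, DESeq2 called 41 genes against 4 in edgeR, and leaving out each library gave 3 to 6. For the presence of BZ, DESeq2 called 24 against 0, and leaving out each library gave 0 to 3, with 3 without CCI replicate 2 and 1 without CCI+YZP replicate 2. Over the 9 pairs of identifier and comparison, the alternatives gave 190 values with the same sign and side of the threshold, 53 with the same sign and an adjusted p of 0.05 or more, and none with the opposite sign. The gene list tests and their alternatives (estimated correlation, fry, block, filter and left-out libraries) were not run, since no identifier had a symbol. At this depth and n, the simulated recovery of 35.8% at 1.5-fold limits what a count of 0 can show. The simulated genes varied independently, without an axis such as the first principal component, so recovery in these libraries may differ.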

Other observations

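The contrasts for the presence of YH or BZ and their regroupings were chosen only after the results were seen. ENSRNOG00000013548 was low in each of the 6 libraries of rats that received YH, alone or within YZP, at 6.53 ± 2.72 CPM (4.35 to 11.6), and high in each of the 6 ligated libraries without it, at 77.6 ± 37.5 CPM (39.3 to 131), while sham stood at 38.6 ± 22.0 CPM (SD, n = 3). The log2 fold change for the presence of YH was -3.64 (SE 0.399, edgeR adjusted p = 0.00573), and the call held without each library in turn (0.00126 to 0.0236). ENSRNOG00000021824 was higher with YH, at 140 ± 13.9 against 103 ± 16.3 CPM (log2 fold change 0.46, SE 0.0569, adjusted p = 0.0078), and also held (0.00189 to 0.0453). Its ranges overlapped, with 115 CPM the lowest with YH and 125 CPM the highest without. CCI+YH stood at 131 ± 15.7 CPM, CCI at 116.5 ± 9.02 and CCI+BZ at 88.8 ± 2.35, so part of the pooled gap came from the low level in CCI+BZ. ENSRNOG00000010706 was higher with YH in the pooled contrast (log2 fold change 0.60, SE 0.0806, adjusted p = 0.016). The level was 22.1 ± 1.74 CPM in CCI+YZP but 14.5 ± 1.73 in CCI+YH, against 11.3 ± 0.679 in CCI and 12.4 ± 1.68 in CCI+BZ. Ranges overlapped (13.4 CPM lowest with YH, 14.3 highest without), and CCI+YH was not called against CCI (edgeR adjusted p = 0.744). The pooled call was lost without CCI replicates 1 or 2, CCI+YZP replicates 1 or 3, or CCI+BZ replicates 1 or 2, with an adjusted p of up to 0.0838. In all 4 genes were called, 3 higher and 1 lower.

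The hypothesis that the YH component may account for these genes could not be tested apart from the calls that prompted it, since all 4 genes had already been called in a comparison of the same libraries. Among 100 splits of the 12 ligated libraries, 2 called as many genes, the real split included, which for this reason excludes nothing. The highest other split called 658 genes, many times the real count. It set 6 of the 7 ligated libraries above 0 on the first principal component against the other 6 libraries, the largest gap on this component of the 100 splits (30.2, against 2.12 for the real one), which points to that structure of the samples. For the presence of BZ, edgeR called 0 genes, with 950 at an unadjusted p under 0.05, and DESeq2 called 24. A count of 0 is reached by all 100 splits whatever the data, so this comparison says nothing about chance, and the highest other split, also the one with the largest gap (32.9, against 16.1 for the real one), called 880. The contrast was picked on the same libraries, so it remains a hypothesis.

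For the other comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. The real split and the highest other called 3 and 2 genes for CCI against sham, 1 and 1 for CCI+YZP against CCI, 0 and 0 for CCI+YH and for CCI+BZ against CCI, and 0 and 1 for CCI+YZP against CCI+YH. Against sham they called 11 and 0 for CCI+YZP, 7 and 1 for CCI+YH, and 0 and 1 for CCI+BZ. For the departure from additivity the real split called 0 genes and the highest other of 30 splits 2, and a comparison with a count of 0 says nothing about chance.

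In 122 of the tested genes, libraries of the same group spanned at least 4 log2 units while some library reached at least 5 CPM. Such genes numbered 41 in sham, 35 in CCI, 49 in CCI+YZP, 49 in CCI+YH and 56 in CCI+BZ. Of the 103 genes with an absolute log2 fold change of at least 2 and an unadjusted p under 0.05 in CCI against sham, 25 (24.3%) were of this kind, the lowest share of the 11 comparisons. The highest were 51.2% (22 of 43) for CCI+YZP against CCI+YH, 47.4% (18 of 38) for CCI+YZP against CCI+BZ and 40.7% (22 of 54) for CCI+BZ against CCI. Of the 18 genes called in any comparison 0 were. This says little, since such genes made up 0.738% of those tested and a large spread within a group makes a call unlikely.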
